A study of Mus musculus with 36 samples.

How the data were processed

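Total RNA from mouse NIH3T3 fibroblasts carrying an Erbb2 transgene was profiled on 36 dual-colour cDNA arrays. The transgene was under tet-off control, a system in which tetracycline shuts the transgene down. Per the labels, channel 1 held RNA of cells after 1, 2, 4, 12 or 24 h or 3, 5 or 7 days of tetracycline, or of untreated cells, with 4 arrays per group. Channel 2 held RNA of untreated Erbb2 cells on every array. The labels' protocols conflict with this, since they speak of individual organs and of a reference pool from 6 control animals, so what the ratios are taken against is not fully settled; the named sources were followed. Replicates 1 and 2 of each group carried channel 1 in Cy5 and replicates 3 and 4 carried it in Cy3.

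The deposited values are log2 ratios of the 2 channels. The labels name no software, background correction or normalization, and the files do not say which channel is the numerator. A shared ceiling at a ratio of 100000 (16.61 on the log2 scale) sat lower on most arrays by a constant of their own, so a single constant per array had been subtracted from most columns. The 2807 values at the ceiling were set to missing, and each array was centred on its median. The medians before centring ran from -0.519 (3d replicate 4) to 0.747 (untreated replicate 1). Arrays carry no read depth; the number of arrays limits the precision, and the spread between arrays that enters each p-value may be technical, since the labels do not say whether replicates are separate cultures.

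Several features of the deposited columns were found by checks of the values. The columns of untreated replicates 1 and 2 differed by a constant of 0.771 over 19840 values with an SD of 0.0005, while the next highest correlation of any pair of arrays was 0.449. They were counted as 1 array, which left 3 untreated arrays and 35 arrays in all. In all 8 arrays of 5 and 7 days the values slid against the probe rows, by 1 further row at each of 4 points, the earliest between rows 6039 and 6056, and 5d replicate 1 was displaced by 1 row more along its whole length. These values were moved back, and 645 probes per array around the slide points and from row 20181 on were left out. In 6 simulated arrays with 4 dropped rows, 99.34% to 99.85% of rows were placed right. Before the move, pairs of probes for 1 gene past row 6056 had a Spearman rho of 0.003 at 7 days, against 0.060 when the annotation was shifted by 3 rows, and after the move 0.096 unshifted. At 5 days the values were 0.038 and 0.074 before and 0.058 after, so the gain there was small. This correlation is across genes within groups, and genes are not independent replicates.

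Arrays with channel 1 in Cy3 were multiplied by -1, so that a positive value stands for more RNA in channel 1. The rule fixed beforehand, the mean correlation of arrays of opposite dye in the treated groups, was undecided (Spearman rho -0.0159, Pearson r 0.0159). Turning was therefore chosen after the data were seen, from probes beyond 1 log2 unit in both Cy5 arrays. At 2 h 61.1% of these had the opposite sign in both Cy3 arrays and 24.5% the same sign, and at 5 days 58.4% and 14.8%. The opposite sign also led at 1 h (38.3% and 28.2%), 24 h (29.7% and 19.6%) and 7 days (40.3% and 21.7%). The balance went the other way at 4 h (36.1% opposite, 42.0% same), 12 h (19.4% and 39.6%) and 3 days (14.8% and 47.8%). In the untreated arrays the shares were 5.6% opposite and 73.0% same. Per the labels these hold the same RNA in both channels, which would leave only a dye bias of the probes. The same sign is then what ratios taken by dye give, the case in which turning is right. This reading would not hold if channel 1 of these arrays held another line. A dye bias shared by all arrays would also give positive correlations with treated arrays before turning. Untreated replicate 3 instead correlated at -0.1859 with 2h replicate 4 (Cy3) and -0.1351 with 4h replicate 1 (Cy5). With 3d replicates 2 (Cy5) and 4 (Cy3) it correlated at 0.1084 and 0.0799. The untreated arrays therefore do not decide the direction. Treated over untreated was assumed and is not settled by any file.

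Differences were tested with limma 3.58.1 in R 4.3.3. All 35 arrays entered 1 linear model with a mean per group and a dye effect per probe, followed by eBayes. After the merging the untreated group held 1 Cy5 array and 2 Cy3 arrays. Once turned, the Cy5 array correlated with the Cy3 arrays at -0.449 and -0.38. A dye difference of the untreated arrays beyond the common dye effect does not cancel, and can shift every comparison with them. The alternative with a dye effect for each group allows for it. A probe needed at least 3 values in each group compared. P-values were adjusted with the Benjamini-Hochberg method over the probes tested, and an adjusted p under 0.05 was called. Each time was compared with the untreated arrays. Further tests were a moderated F-test for a change at any time, 3 contrasts between parts of the course (early: 1, 2 and 4 h; middle: 12 and 24 h; late: 3, 5 and 7 days), and the untreated arrays against 0. Log2 differences are given with the standard error (SE) of the model.

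Probes were named through the platform's gene identifiers and a reference gene table (GRCm38.p6). A single symbol was found for 14030 probes and 13994 of them matched by identifier; 6320 had none. Before the data were examined, 28 gene lists were fixed. They were tested with cameraPR (two-sided, preset correlation 0.01) on gene-level values, probes of a gene being averaged, with adjustment over all 224 pairs of list and time. The test was repeated with a correlation estimated per list. The test fry was also run on genes measured on all arrays, and its results are not given here. Members were counted over all genes tested and adjusted over the list alone.

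Genes named in the text follow a rule fixed beforehand: the 6 largest rises and falls per time among called probes whose difference from the untreated mean had 1 sign in all measured arrays, up to 4 members of each list, the 5 smallest p of the F-test, the 4 largest rises and falls of each contrast between parts of the course, and Egfr, Erbb2, Erbb3 and Erbb4. List members given at gene level outside that rule were chosen after their values were seen.

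Code was tested on simulated data with 100 probes changed by 1 and 100 by 2 log2 units. For the 2 h comparison (18505 probes) 22% and 64% were recovered with 9 unchanged probes called, and for 5 days (17332 probes) 26% and 72% with 4. For the contrast of early and middle times (15165 probes) recovery was 74% and 96% with 9 unchanged probes called. In a simulated shift of the extracellular matrix list by 0.5, over 224 pairs of list and time, that list had an adjusted p of 1.1e-15 and 0 others were called by cameraPR. The simulated noise was independent between probes and equal in spread on all arrays. It therefore does not show how often lists are called falsely in the real data. There, shuffled array labels gave up to 48 list calls.

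Alternatives fixed beforehand were no dye term, a replicate block, values not centred, quantile normalization, other minimum numbers of values, robust eBayes, averaged dye pairs, only the arrays of the groups compared, a test against 0, and each replicate left out in turn (the merged untreated array stays when replicate 1 or 2 of every group is left out). Those chosen after the data were seen were rows as deposited, ceiling values kept, arrays not turned, a dye effect for each group, array weights, and leaving out the 5 and 7 day arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for preparation and figures.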

Results

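The series followed NIH3T3 mouse fibroblasts after tetracycline, which in this tet-off system is meant to shut down an Erbb2 transgene. Erbb2 is a receptor tyrosine kinase of the epidermal growth factor receptor family that signals through the ERK and AKT pathways. There were 4 arrays at each of 8 times, 1, 2, 4, 12 and 24 h and 3, 5 and 7 days, and 3 distinct untreated arrays. Between 17508 and 20010 features per array carried a value. The depth of an array is not given by the files, and the number of arrays limits the precision. Differences below are log2 values at a time minus the untreated arrays. Their direction rests on turning the Cy3 arrays, which was assumed and is not settled. Without turning, 39 of 153 results for named genes had the same sign, and limma called 5 of the 153, all with the opposite sign. Values of single genes are those of 1 probe unless a gene mean is stated, and counts within lists are of genes, with the probes of a gene averaged. The arrays of 3, 5 and 7 days stand apart: the interquartile range of their log2 values was 0.700 to 1.44, against 0.358 to 0.510 on the arrays of 1 to 24 h and 0.496 to 0.713 on the untreated. Estimated array weights were 0.092 to 0.623, against 1.066 to 3.798 and 0.277 to 1.678. The model pools the variance of all arrays, so counts of early and late times are not on 1 scale of precision, and this difference in spread moves with the late contrasts. Gene lists and the rule for named genes were fixed before the data were examined.

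Per the labels, the untreated arrays held untreated Erbb2 cells in both channels. The series' design text names 2 different untreated lines as control, so channel 1 of these arrays could hold another line, and shifts from 0 or differences from these arrays would then include a difference between lines. In them Xbp1, a transcription factor of the unfolded protein response, averaged -2.66 against 0 (SE 0.49, adjusted p = 0.0408). Zkscan1, a zinc finger gene, averaged -1.99 (SE 0.26, adjusted p = 0.000665), and the splicing cofactor Son averaged -1.75 (SE 0.35, adjusted p = 0.0439). Of 18829 probes, 14 differed from 0, 2 above and 12 below. Rises of Xbp1, Zkscan1, Son, Max, H1f10, Them7 and Klhdc7a at the times below carry this level: tested against 0, their calls ended, and the sign of Zkscan1 at 1, 2 and 4 h was the opposite. The calls of Cfap206 at 2 h and Matr3 at 4 h ended too. Each is given with its treated mean. Other probes of Zkscan1, Son and Max lay at -0.01, 0.06 and -0.02 in the untreated arrays and did not pass. With a dye effect for each group the untreated calls of Xbp1, Son, Max and Cfap206 ended. Leaving out replicate 1, 2, 3 or 4 of every group gave 1, 1, 1 or 3 calls, values not centred 6, quantile normalization 80 (56 above, 24 below) and array weights 1043.

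At 1 h, the earliest time, genes of the extracellular matrix were lower. Decorin (Dcn), a collagen-binding proteoglycan, fell by 1.84 on the log2 scale (SE 0.20, adjusted p = 7.42e-06), with a mean of -1.87 ± 0.09 (SD, n = 4) against 0.02 ± 0.18 (SD, n = 3) in untreated arrays. The secreted metalloprotease Adamts1 fell by 2.22 (SE 0.24, adjusted p = 7.42e-06), lysyl oxidase (Lox), which cross-links collagen, fell by 1.82 (SE 0.23), periostin (Postn) fell by 1.84 (SE 0.28) and Col1a1 fell by 1.58 (SE 0.24). Of 31 measured matrix genes, 9 fell and 22 did not pass; adjusted over the list alone 13 fell. The 9 were Col1a1, Col1a2, Col3a1, Col5a2, Col6a1, Lox, Postn, Dcn and Fbln2. The list had a median of -0.30 (cameraPR adjusted p = 1.3e-29, and adjusted p = 2.67e-14 with an estimated correlation). Naprt, an enzyme of NAD synthesis, fell by 1.76 (SE 0.23). Gapdh, a glycolytic enzyme often used as a reference, rose by 1.44 on 1 probe (SE 0.28, adjusted p = 0.0146), while its gene mean of 1.29 missed the threshold (adjusted p = 0.277), and Mid1, a ubiquitin ligase, by 1.26 (SE 0.24), although 2 other Mid1 probes did not pass. Epb41l3 rose by 2.54 (SE 0.53). H1f10, Zkscan1 and Max also passed, with treated means of 0.82, -0.20 and 0.29 and untreated means of -1.93, -1.94 and -1.45; other probes of Zkscan1 and Max differed by -0.01 and 0.16 and did not pass. Among 9 measured ERK targets, adjusted over the list alone 2 rose, while all 9 missed the threshold over all genes (median 0.39, adjusted p = 0.0435, and adjusted p = 0.0549 with an estimated correlation). For cholesterol synthesis, 2 of 9 rose adjusted over the list alone and all 9 missed it over all genes (median 0.38, adjusted p = 0.0338, and adjusted p = 0.0827 with an estimated correlation). Ribosomal protein genes had a median of -0.28 over 35 members, of which 1 fell adjusted over the list alone (adjusted p = 2.03e-05, and adjusted p = 0.163 with an estimated correlation). The 7 reference genes had a median of 0.23, with 1 rising adjusted over the list alone (adjusted p = 0.0444, and adjusted p = 0.118 with an estimated correlation). In all, 36 of 18269 probes (26 genes) passed, 10 higher and 26 lower, 24 of them by at least 2-fold. Without untreated replicate 1 the count was 386, without untreated replicate 4 it was 19, and without 1h replicate 1 it was 22. With a dye effect for each group it was 96, with values not centred 14 and with quantile normalization 182. Array weights gave 963, and with only the arrays of the 2 groups compared limma called 0 (1115 at an unadjusted p under 0.05).

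At 2 h the immediate early transcription factor Egr1 fell by 2.24 on the log2 scale (SE 0.25, adjusted p = 8.99e-05), while metabolic and cytoskeletal genes were higher. The lysosomal protease cathepsin L (Ctsl) rose by 1.54 (SE 0.19, adjusted p = 8.99e-05), with a mean of 1.95 ± 0.24 (SD, n = 4). The replication clamp Pcna rose by 1.30 (SE 0.21), the cholesterol enzyme Hmgcs1 by 1.35 (SE 0.31), metallothionein Mt1 by 1.80 (SE 0.38) and the splicing protein gene Snrnp70 by 1.91 (SE 0.41), another probe of which was at 0.10 and did not pass. Hmgcs1 lost its call with a dye effect for each group. Matrix genes stayed lower: 6 of 31 fell and 25 did not pass, and adjusted over the list alone 7 fell and 2 rose (median -0.22, adjusted p = 5.32e-10, and 5.31e-05 with an estimated correlation). Postn fell by 2.02 (SE 0.28), Adamts1 fell by 1.72 (SE 0.24), Dcn fell by 1.28 (SE 0.20), and Col3a1 and Lox fell by 1.26 each, Lox with a gene mean of -0.81 and other probes at -1.01, which passed, and -0.15.

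Several lists rose at 2 h. Of 28 actin and contractile genes 2 rose, Actb with a gene mean of 0.96 and profilin (Pfn1) with 0.87, and 26 did not pass, with 2 adjusted over the list alone (adjusted p = 0.00167, and 0.000514 with an estimated correlation). Of 20 glycolytic genes 2 rose, Aldoa with a gene mean of 0.78 and Pkm with 1.30, and 18 did not pass, with 4 rising adjusted over the list alone (adjusted p = 0.00834, and 0.00618 with an estimated correlation). Gapdh rose by 1.86 and 1.56 on 2 of 3 probes, with the other at 0.70, while its gene mean of 1.39 missed the threshold (adjusted p = 0.140). For the 7 reference genes, 2 rose and 5 did not pass, with 3 adjusted over the list alone (adjusted p = 3.75e-07, and 2.46e-05 with an estimated correlation). For G1/S genes 1 of 32 rose and 31 did not pass, 1 adjusted over the list alone (median 0.28, adjusted p = 0.0127, and 0.00473 with an estimated correlation), and 1 of 9 ERK targets rose, 1 adjusted over the list alone (adjusted p = 0.0234, and 0.0273 with an estimated correlation). G2/M genes had a median of 0.32 with all 31 members missing the threshold (adjusted p = 0.0332, and adjusted p = 0.0549 with an estimated correlation). The remaining rises were lost with an estimated correlation. These were cholesterol synthesis, 1 of 9 rising and 2 adjusted over the list alone (adjusted p = 0.0338, and adjusted p = 0.0824 with an estimated correlation), and oxidative phosphorylation, 1 of 27 (Sdhd, by 0.68) and 2 adjusted over the list alone (adjusted p = 0.000891, and adjusted p = 0.0635 with an estimated correlation). Heat shock and proteasome genes had 1 of 21 rising (Hspd1, with a gene mean of 0.68) and 3 adjusted over the list alone (adjusted p = 0.00167, and adjusted p = 0.0635 with an estimated correlation). The unfolded protein list had a median of 0.35 over 21 members with 3 rising adjusted over the list alone (adjusted p = 0.00621, and adjusted p = 0.0655 with an estimated correlation), and lysosomal genes had 1 of 21 rising, 1 adjusted over the list alone (adjusted p = 0.00621, and adjusted p = 0.139 with an estimated correlation). Immediate early genes were called lower with a median of 0.03 and a mean of -0.06, so the median and the test differ in sign: Egr1 fell, also adjusted over the list alone, and 12 of 13 did not pass (adjusted p = 0.0272, and adjusted p = 0.0549 with an estimated correlation). Son, Cfap206 and Zkscan1 also passed, with treated means of 0.24, 0.34 and -0.17 and untreated means of -1.73, -1.55 and -1.94; other probes of Son and Zkscan1 differed by 0.14 and -0.19, and those of Cfap206 by 1.63 and -0.39, none passing. Hsp90aa1, for a heat shock protein, rose by 1.18 on 1 probe, with another at -0.26 and a gene mean of 0.46 that missed the threshold. In all, 101 of 18505 probes (66 genes) passed, 77 higher and 24 lower, 73 by at least 2-fold. Leaving out 2h replicate 1, 2, 3 or 4 gave 54, 60, 67 or 52, and leaving out untreated replicate 1, 3 or 4 gave 424, 44 or 58. With a dye effect for each group the count was 240, with values not centred 14 (7 higher, 7 lower) and with quantile normalization 332. Array weights gave 1518, and with only the arrays of the 2 groups compared limma called 0 (1634 at an unadjusted p under 0.05).

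At 4 h Egr1 fell by 2.90 on the log2 scale (SE 0.25, adjusted p = 1.91e-06). Adamts1 fell by 1.84 (SE 0.24) and Postn fell by 1.56 (SE 0.28). The lysosomal membrane glycoprotein gene Glmp fell by 2.21 (SE 0.30, adjusted p = 0.000288), the carboxypeptidase gene Cpz fell by 1.35 (SE 0.29) and Naprt fell by 1.14 (SE 0.23). Tm4sf1, a membrane protein gene, rose by 1.62 (SE 0.32, adjusted p = 0.0214), Gapdh by 1.59 (SE 0.28) and 1.28 on 2 of 3 probes (other probe 1.06; gene mean 1.39, adjusted p = 0.266), and the enolase gene Eno1b by 1.12 (SE 0.24). Matr3, for a nuclear matrix protein, rose by 1.43 (SE 0.31; treated mean 0.47), a call that a dye effect for each group ended. Of 31 matrix genes 5 fell and 26 did not pass; adjusted over the list alone 7 fell and 1 rose (median -0.14, adjusted p = 6.57e-07, and 0.00156 with an estimated correlation). Of 28 actin genes 2 rose, 2 adjusted over the list alone (median 0.31, adjusted p = 0.000105, and 2.33e-05 with an estimated correlation), and of 7 reference genes 1 rose, 3 adjusted over the list alone (adjusted p = 1.59e-06, and 7.33e-05 with an estimated correlation). G2/M genes had a median of 0.25 with all 31 missing the threshold (adjusted p = 0.00621, and 0.00882 with an estimated correlation), and cholesterol genes 0.34 with 1 of 9 rising adjusted over the list alone (adjusted p = 0.0107, and 0.0469 with an estimated correlation). ERK targets (median 0.24, adjusted p = 0.0435, and adjusted p = 0.0549 with an estimated correlation) had all 9 members missing it, and heat shock genes (median 0.17, adjusted p = 0.0389, and adjusted p = 0.245 with an estimated correlation) had 1 of 21 rising adjusted over the list alone. In the unfolded protein list 1 of 21 rose, 1 adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.0808 with an estimated correlation). That was Xbp1, with a treated mean of 0.72 against -2.52 untreated. Immediate early genes were called lower with a median of -0.05 but a mean of 0.08, which differ in sign; Egr1 was the 1 of 15 that fell, also adjusted over the list alone (adjusted p = 0.00621, and 0.0148 with an estimated correlation). Zkscan1 passed with a treated mean of -0.18, and its other probe differed by -0.92. In all, 39 of 18617 probes (26 genes) passed, 27 higher and 12 lower, 29 by at least 2-fold. Leaving out 4h replicate 1, 2 or 3 gave 10, 20 or 17, and leaving out untreated replicate 1, 3 or 4 gave 312, 13 or 18. A dye effect for each group gave 89, values not centred 4 (1 higher, 3 lower) and quantile normalization 199. Array weights gave 691, and with only the arrays of the 2 groups compared limma called 0 (1010 at an unadjusted p under 0.05).

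At 12 and 24 h few probes passed, and Egr1 and Postn were the named falls. Egr1 fell by 2.21 on the log2 scale at 12 h (SE 0.25, adjusted p = 0.000224) and fell by 3.32 at 24 h (SE 0.25, adjusted p = 1.27e-07), with a mean of -3.67 ± 0.45 (SD, n = 4) at 24 h. Postn fell by 1.79 (SE 0.28, adjusted p = 0.00561) and fell by 1.74 (SE 0.28, adjusted p = 0.00599). Mid1 rose by 1.30 at 24 h (SE 0.24), where 2 other probes were at -0.58 and 0.83. Zkscan1 passed at both times with treated means of 0.09 and 0.10, and its other probe differed by -0.26 and -0.04. Of 15 immediate early genes Egr1 fell and 14 did not pass at 12 h, with 3 falling adjusted over the list alone (median -0.12, adjusted p = 2.18e-06, and 2.46e-05 with an estimated correlation). The mean of the list over its genes on the arrays was -0.47 at 12 h and -0.31 at 24 h against -0.41 in the untreated arrays. At 24 h Egr1 fell and 12 of 13 did not pass, with 4 falling adjusted over the list alone (median -0.17, adjusted p = 3.9e-09, and 5.49e-08 with an estimated correlation). G2/M genes had a median of 0.26 at 12 h with all 30 missing the threshold (adjusted p = 0.000805, and 0.00116 with an estimated correlation). Of 31 matrix genes at 12 h, 1 fell and 30 did not pass, with 2 falling adjusted over the list alone (adjusted p = 0.0411, and adjusted p = 0.240 with an estimated correlation). Ribosomal protein genes had medians of -0.20 at 12 h (adjusted p = 0.00621, and adjusted p = 0.423 with an estimated correlation) and -0.12 at 24 h (adjusted p = 0.0392, and adjusted p = 0.555 with an estimated correlation), and all members missed the threshold; against 0 the list at 24 h was called higher. Reference genes had medians of 0.17 at 12 h, with 1 of 7 rising adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.0635 with an estimated correlation), and 0.06 at 24 h, with 2 (adjusted p = 0.0234, and adjusted p = 0.0672 with an estimated correlation). In all, 3 of 18151 probes passed at 12 h, 1 higher and 2 lower, and 5 of 18125 at 24 h, 3 higher and 2 lower. Without untreated replicate 1 there were 330 and 274, and without untreated replicate 4 there were 7 at 12 h. A dye effect for each group gave 33 and 20, values not centred 1 and 1, and quantile normalization 40 and 15; other splits of the same arrays gave up to 17 and 46. Array weights gave 707 and 716, and with only the arrays of the 2 groups compared limma called 0 at both times (807 and 850 at an unadjusted p under 0.05). Chance alone gives a share of 0.05 of the probes tested, and both counts lie below it.

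At 3 days the direction of the matrix genes was the opposite of that at 1 h. Of 31 matrix genes 3 rose and 28 did not pass, and adjusted over the list alone 8 rose (median 0.18, adjusted p = 0.00118, and adjusted p = 0.0545 with an estimated correlation). The 3 were Col6a1, Dcn and Col1a1, with gene means 0.95, 0.87 and 0.61 above the untreated arrays. Egr1 fell by 1.46 on the log2 scale (SE 0.25, adjusted p = 0.00744). The fatty acid binding protein gene Fabp5 fell by 1.74 (SE 0.40), the endoplasmic reticulum chaperone gene Dnajc3 fell by 1.55 on 1 probe (SE 0.36; gene mean -1.18, which missed the threshold), the nucleolar protein gene Wdr36 fell by 3.19 (SE 0.58), and the sialidase gene Neu1 fell by 1.85 (SE 0.43), for which another probe was at 0.41. Aamp fell by 1.79 (SE 0.38), with another probe at 0.01. Perp, a p53 target, rose by 0.77 on 1 probe (SE 0.17; gene mean 1.06, which missed the threshold), the ubiquitin ligase gene Mib1 by 2.51 (SE 0.43) and Wdr60 by 3.07 (SE 0.53). Nup214, of the nuclear pore, rose by 2.39 on a single probe, and its other probes were at -0.93 and -1.36. Cfap206, Them7 and H1f10 passed with treated means of 1.74, 1.52 and 0.66 and untreated means of -1.63, -2.32 and -1.93; other probes of Cfap206 differed by 2.37, which passed, and -0.12, and that of Them7 by -0.43. Of 35 ribosomal protein genes 2 fell and 33 did not pass, with 7 falling adjusted over the list alone (median -0.45, adjusted p = 5.01e-05, and adjusted p = 0.190 with an estimated correlation). Of 30 G1/S genes 1 fell, 1 adjusted over the list alone (median -0.27, adjusted p = 0.0375, and 0.0265 with an estimated correlation). Heat shock genes had 1 of 20 falling and 4 adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.163 with an estimated correlation), and the 7 ERBB receptor and ligand genes had a median of 0.31 with all 7 missing the threshold (adjusted p = 0.0184, and adjusted p = 0.159 with an estimated correlation). In all, 132 of 17085 probes (89 genes) passed, 68 higher and 64 lower, 81 by at least 2-fold. Leaving out 3d replicate 1, 2 or 3 gave 421, 593 or 296, and leaving out untreated replicate 1, 3 or 4 gave 805, 31 or 22. The 3d arrays kept their sign between dyes more often than they turned it, and a dye effect for each group gave 444 calls. Quantile normalization left 4 (3 higher, 1 lower) and values not centred 21 (14 higher, 7 lower). Array weights gave 198 (57 higher, 141 lower), which turns the balance, and with only the arrays of the 2 groups compared limma called 0 (649 at an unadjusted p under 0.05). That count lies below the share of 0.05 of the probes tested that chance alone gives. Other splits of the same arrays gave up to 3238.

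At 5 days matrix genes were higher and genes of the ribosome lower. The regulator Cebpd, a transcription factor of adipocyte differentiation, rose by 1.82 (SE 0.19, adjusted p = 1.15e-06), the acute phase gene Saa3 by 2.17 (SE 0.34, adjusted p = 0.000238) and gelatinase A (Mmp2) by 1.12 (SE 0.24). The cell cycle gene Ccna2, cyclin A2, fell by 1.75 on the log2 scale (SE 0.24, adjusted p = 6.11e-05), with a mean of -1.57 ± 0.30 (SD, n = 4); another probe was at -0.72 and did not pass. Nucleophosmin (Npm1) fell by 1.48 (SE 0.26) and Rpl13a fell by 1.46 (SE 0.22). Rpl14 fell by 1.29 (SE 0.19) and Rpl4 fell by 1.22 (SE 0.17) on single probes, while their gene means of -0.42 and -0.64 missed the threshold. Of 35 ribosomal protein genes 5 fell, Rpl5, Rpl13a, Rpl19, Rplp0 and Rps20, and 30 did not pass, with 17 falling adjusted over the list alone (median -0.69, adjusted p = 4.34e-20, and 0.000974 with an estimated correlation). For oxidative phosphorylation 1 of 26 fell (Uqcrh, by 0.98), with 6 adjusted over the list alone (median -0.39, adjusted p = 6.57e-07, and 0.00356 with an estimated correlation). Of 30 matrix genes 6 rose and 24 did not pass, with 11 rising adjusted over the list alone (median 0.33, adjusted p = 2.37e-06, and 0.00296 with an estimated correlation).

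Other lists moved at 5 days too. Of 32 G1/S genes 2 fell, 4 adjusted over the list alone (median -0.11, adjusted p = 0.00413, and 0.00106 with an estimated correlation), and 1 of 28 G2/M genes, 1 adjusted over the list alone (median -0.13, adjusted p = 0.0338, and adjusted p = 0.0549 with an estimated correlation). Ribosome biogenesis had 1 of 21 falling and 3 adjusted over the list alone (adjusted p = 0.0284, and adjusted p = 0.232 with an estimated correlation). The mitochondrial chaperone genes Hspe1 and Hspd1, with gene means of -1.28 and -0.91, were the 2 of 20 heat shock genes that fell, with 3 adjusted over the list alone (adjusted p = 0.00997, and adjusted p = 0.121 with an estimated correlation). Among adipocyte genes 1 of 11 rose, Cebpd, 1 adjusted over the list alone (median 0.33, adjusted p = 0.0242, and adjusted p = 0.0635 with an estimated correlation). S100a6, a calcium-binding protein gene, fell by 1.53 (SE 0.25), vimentin (Vim) fell by 1.11, the serine synthesis gene Psat1 fell by 1.68, the transcription factor gene Sox5 fell by 1.85 and the endothelial cadherin Cdh5 fell by 1.52 on 1 probe (gene mean -1.03, which missed the threshold). Peptidyl-prolyl isomerase (Ppia), a common reference, fell by 0.98 (SE 0.18). The class I antigen H2-K1 rose by 1.82, the interferon-induced Rsad2 by 0.90 on 1 probe with another at -0.38 (gene mean 0.38, which missed the threshold), the chaperone calreticulin (Calr) by 0.99 and the TGF-beta co-receptor endoglin (Eng) by 1.30, another probe of which was at 0.04. Rgs19 rose by 2.65. Pomgnt1 fell by 1.82, but its sign, like those of S100a6, Vim and Calr, was the opposite with the rows as deposited. Man1b1 rose by 2.63, with another probe at 0.04, and Pdcd1 fell by 1.76, calls that ended with a dye effect for each group. Xbp1, Klhdc7a and Them7 passed with treated means of 0.87, 0.86 and 0.22 against untreated means of -2.52, -1.67 and -2.32; another probe of Them7 differed by -0.52. In all, 390 of 17332 probes (230 genes) passed, 220 higher and 170 lower, 249 by at least 2-fold. Without untreated replicate 1 there were 864 and without untreated replicate 4 there were 204. A dye effect for each group gave 622, and the rows as deposited gave 87. Quantile normalization turned the balance to 88 higher and 182 lower, and values not centred gave 120. Array weights gave 686 (320 higher, 366 lower), which also turns it, and with only the arrays of the 2 groups compared limma called 0 (1324 at an unadjusted p under 0.05).

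At 7 days matrix genes were higher and several early response genes rose. Dcn was 1.56 above the untreated arrays (adjusted p = 7.5e-05), Lox 1.24 and Col1a2 1.07 (gene means 1.21 and 1.32). Ier3, an early response gene that was also higher at 2 h (1.16) and 5 days (0.83), rose by 1.41 (SE 0.21, adjusted p = 0.000442), the AP-1 member Junb by 1.30 (SE 0.21, adjusted p = 0.00129), the antiproliferative gene Btg2 by 1.24 (SE 0.17) and Ier2 by 0.91 (SE 0.19). The growth arrest gene Gas1 rose by 1.01 (SE 0.17) and the haem oxygenase Hmox1 by 1.00 (SE 0.17). The replication factors Mcm5 and Uhrf1 fell by 1.79 (SE 0.42) and 1.5 (SE 0.35), topoisomerase Top2a fell by 1.89 (SE 0.46), and gelatinase B (Mmp9) fell by 1.43 on 1 probe (SE 0.25), with another at 0.10 and a gene mean of -0.37 that missed the threshold. The nucleotide reductase gene Rrm2 rose by 2.05 on 1 probe (SE 0.44; gene mean 1.02, which missed the threshold). Of 31 matrix genes 10 rose and 1 fell, Fn1, and 20 did not pass, with 14 rising and 1 falling adjusted over the list alone (median 0.49, adjusted p = 1.75e-17, and 2.77e-08 with an estimated correlation). Of 13 immediate early genes 3 rose and 10 did not pass, with 4 rising adjusted over the list alone (median 0.48, adjusted p = 0.00167, and 0.00456 with an estimated correlation). Egr1 was not among the 13, since its probe lies in the rows left out at 5 and 7 days. The list is therefore not the same set of genes as at 24 h. Ribosomal protein genes had 3 of 35 falling, 5 adjusted over the list alone (median -0.50, adjusted p = 5.82e-08, and adjusted p = 0.0655 with an estimated correlation). Oxidative phosphorylation had a median of -0.17 with 2 of 26 falling adjusted over the list alone (adjusted p = 0.0332, and adjusted p = 0.245 with an estimated correlation). Psat1 fell by 2.06, Scd1, a lipid desaturase gene, fell by 0.85, Ncbp1 fell by 2.30 (its sign was the opposite with the rows as deposited, and another probe was at -0.04), Xpa, of nucleotide excision repair, fell by 2.46 (another probe at -0.15), Gprc5c fell by 2.28, Eri1 fell by 2.05 and Lrch4 fell by 2.61, for which other probes were at 0.40 and -0.47. Txnrd2 rose by 4.41, Rtf1 by 3.27, Acbd3 by 2.63 and 4921536K21Rik by 3.52, and Cep95 by 3.79, a call that ended with a dye effect for each group. Other probes, none passing, were at 0.87 for Txnrd2, 0.57 and -0.40 for Rtf1, 0.43 for Acbd3 and -0.32 for Cep95. Xbp1 passed with a treated mean of 0.26. In all, 196 of 16895 probes (142 genes) passed, 108 higher and 88 lower, 124 by at least 2-fold. Leaving out untreated replicate 1, 3 or 4 gave 698, 75 or 70, and a dye effect for each group gave 484. Values not centred gave 30 (12 higher, 18 lower) and quantile normalization 68 (25 higher, 43 lower), which turns the balance. Array weights gave 303 (122 higher, 181 lower), which also turns it, and with only the arrays of the 2 groups compared limma called 0 (942 at an unadjusted p under 0.05). Another split of these arrays gave 437.

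**Figure D1:**
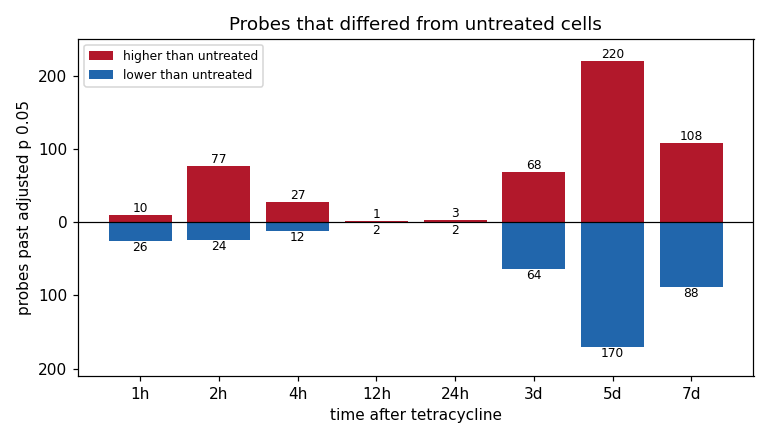
Number of probes with an adjusted p under 0.05 at each time of tetracycline, higher and lower than in the untreated arrays (4 arrays per time, 3 untreated). The count was 3 at 12 h and 390 at 5 days.

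**Figure D2:**
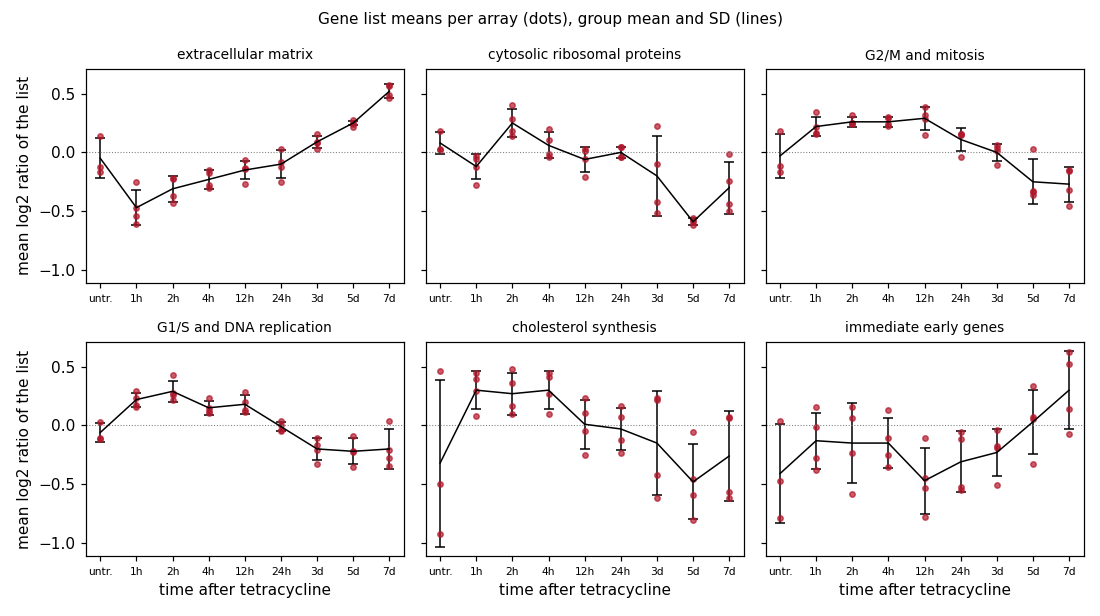
Mean log2 value of 6 gene lists on each array, by time after tetracycline (dots), with the mean and SD of each group (lines; 4 arrays per time, 3 untreated). The extracellular matrix list averaged -0.47 at 1 h and 0.52 at 7 days.

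Over the whole course, matrix genes and a lysosomal protease gave the smallest p-values of the moderated F-test. Dcn had an adjusted p of 8.94e-13, Lox 2.38e-12, Adamts1 4.54e-12, Ctsl 1.03e-11 and Col1a2 5.96e-11. Of 15165 probes, 962 (616 genes) changed at any time. Leaving out replicate 1, 2, 3 or 4 of every group gave 558, 640, 549 or 528, and without the 5 and 7 day arrays there were 389. Values not centred gave 457 and array weights 1987.

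Between the early and the middle times, Col1a2 rose by 1.22 (SE 0.11, adjusted p = 2.71e-08), the matrix protein gene Sparc by 1.15 (SE 0.19), Adamts1 by 1.14 (SE 0.14) and the transcription factor gene Atoh8 by 1.10 (SE 0.14). The matrix list itself was not tested between these parts, and Postn averaged -1.87 at the early and -1.82 at the middle times. Ier3 fell by 1.43 (SE 0.12, adjusted p = 1.39e-08), Psat1 fell by 1.24 (SE 0.23), Gsto1, a glutathione transferase gene, fell by 1.06 (SE 0.25; other probes at -0.50 and -0.24) and the chaperone Hspa5 fell by 1.04 (SE 0.19). In all 105 probes (77 genes) passed, 28 higher and 77 lower. Leaving out replicate 1, 2, 3 or 4 gave 39, 41, 42 or 51, and a dye effect for each group gave 203. Values not centred gave 48, quantile normalization 353 and array weights 555.

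Between the middle and the late times, Lox rose by 1.91 (SE 0.13, adjusted p = 1.66e-10), Postn by 1.89 (SE 0.16), Ccdc80, a matrix-associated protein gene, by 1.82 (SE 0.16) and Dcn by 1.77 (SE 0.12). Ccna2 fell by 1.77 on the log2 scale (SE 0.14, adjusted p = 2.15e-09), the calcium-binding S100a4 fell by 1.64 (SE 0.16), the semaphorin gene Sema4a fell by 1.77 (SE 0.43) and the lipase gene Abhd12 fell by 2.09 (SE 0.52), with another probe at -0.24. In all 603 probes (376 genes) passed, 343 higher and 260 lower. Leaving out replicate 1, 2, 3 or 4 gave 396, 396, 379 or 395. Values not centred gave 293 and quantile normalization 374 (167 higher, 207 lower), which turns the balance, as do array weights with 649 (300 higher, 349 lower).

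From the early to the late times Adamts1 rose by 2.75 (SE 0.13, adjusted p = 2.35e-15), Lox by 2.64 (SE 0.12), Dcn by 2.49 (SE 0.11) and Postn by 1.94 (SE 0.15). Psat1 fell by 2.37 on the log2 scale (SE 0.20, adjusted p = 8.23e-10), Tm4sf1 fell by 2.14 (SE 0.17), Hmgcs1 fell by 1.98 (SE 0.16) and Ctsl fell by 1.93 (SE 0.10). In all 1167 probes (774 genes) passed, 480 higher and 687 lower. Leaving out replicate 1 of every group gave 765, values not centred gave 687 and array weights 1083.

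**Figure D3:**
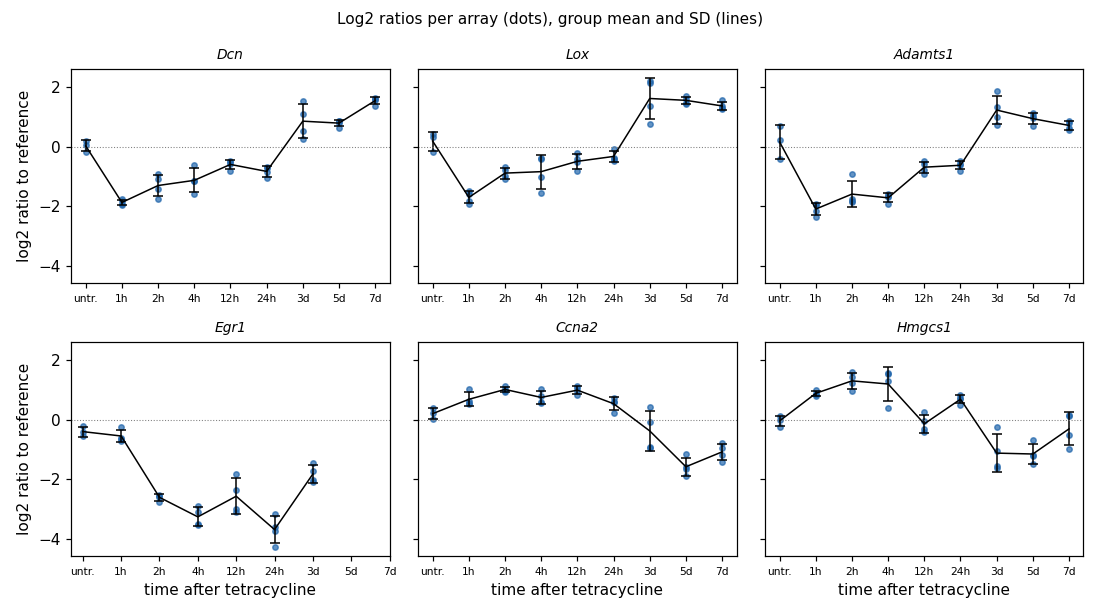
Log2 ratios to the untreated reference for 6 genes on each array by time after tetracycline (dots), with the mean and SD of each group (lines; 4 arrays per time, 3 untreated). Egr1 averaged -3.67 at 24 h and has no values at 5 and 7 days, and Ccna2 averaged -1.57 at 5 days.

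The receptor family itself could be followed only in part. Erbb2 and Erbb4 are not named on the array. Erbb3 was measured by 1 probe and lay at -0.68 (SE 1.42), -0.13 (SE 1.32) and -0.08 (SE 1.41) at 2, 4 and 24 h, which did not pass. Egfr, a dimerization partner of Erbb2, had 5 probes. Probe 8736 rose by 1.5 at 3 days (SE 0.25, adjusted p = 0.00414) and by 2.68 at 5 days (SE 0.25, adjusted p = 2.18e-07), while its other probes lay at 0.11, 0.10, -0.07 and -0.56 at 5 days.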

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

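The tests of the matrix pattern, the tests of the untreated level, the comparisons of the ribosomal list with other lists and the splits of the arrays were chosen only after the result was seen. The test of the row positions, the test without Egr1 and the count of immediate early list means below 0 were written before it. The comparisons within each dye were chosen after it, with 3 statistics tried: the mean of the 2 dyes with the Cy3 arrays turned, the same not turned, and the sizes of the 2 differences alone.

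Matrix genes were lower on the arrays of 1 h. A high level in the untreated arrays is argued against by the list mean against 0, -0.47 at 1 h (SD 0.15, n = 4). The untreated mean was -0.05 (SD 0.17, n = 3). In cameraPR on values against 0 the list was lower than other genes (adjusted p = 4.78e-66). That p treats genes as the units and does not measure the spread between arrays. A dye bias stays open. The turned list mean lay below 0 in 12 of 12 arrays at 1, 2 and 4 h, but such a bias gives this too if the turning is wrong. A bias that is the same on all arrays would leave no difference within a dye. The early minus the untreated arrays differed by -0.542 in Cy5, against 1 untreated array, and by -0.127 in Cy3 (mean -0.334). The exact permutation p was 0.0051 turned, the smallest it can give, and 0.0255 by size alone. The criterion for arguing against such a bias asked for a permutation p under 0.05 both turned and not turned. Not turned the permutation p was 0.168, so the comparison did not decide. A real effect would cancel there if the turning is right, but the turning is itself not settled. A dye bias of the early arrays alone stays open too. The list means of -0.47, -0.31 and -0.23 at 1, 2 and 4 h run opposite to a fall that builds up, but the mean at 4 h minus that at 1 h, 0.241, did not pass (exact permutation p = 0.0857, two-sided), so a build-up is not excluded. A response to tetracycline, through the transgene or through the drug itself, stays open and was not tested, since no array of cells without the transgene is held. The labels name no untreated culture of the same time, so other differences between the cultures cannot be told apart from it.

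Ribosomal protein genes were lower at 5 days. A shift of all abundant transcripts alike is argued against by the ribosomal minus the actin list mean over the 5d arrays, -0.511 (SE 0.055). A shift that leaves out the actin genes stays open: reference genes (-0.253) and oxidative phosphorylation (-0.291) also lay below 0 in 4 of 4 arrays, and the ribosomal list lay lower by differences of -0.333 (SE 0.067) and -0.295 (SE 0.025). Misplaced rows are argued against by the median of -0.961 over 14 ribosomal probes. These lie before the slide points and were not moved in 3 of the 4 arrays of 5 days. A high untreated level is argued against by the list mean against 0, -0.578, where the untreated mean was 0.08. The cameraPR adjusted p of 3.27e-20 compares the list with other genes on values against 0 and does not measure the spread between arrays. A dye bias that is the same on all arrays is argued against by the list means per array, not by the permutation test. The list means at 5 days were -0.589 and -0.554 in Cy5 and -0.621 and -0.579 in Cy3. The untreated ones were 0.023 in Cy5 and 0.186 and 0.028 in Cy3, and those of 1 to 24 h ran from -0.28 to 0.402. The mean difference from the untreated arrays within each dye, -0.651, had a permutation p of 0.0556 (1 not turned, 0.111 by size alone). That is the smallest that 18 permutations can give, so this test could not decide. A dye bias of the 5d arrays alone stays open, since it gives this if the turning is wrong. No biological explanation was tested.

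Immediate early genes were called lower at 12 and 24 h by the list test, although the list means of -0.47 and -0.31 compare with -0.41 ± 0.42 (SD, n = 3) in the untreated arrays. Without Egr1 the list test at 24 h still gave an unadjusted cameraPR p of 0.00236 over its 12 other genes, so in that test the call does not rest on Egr1 alone. That p treats genes as the units and does not show that the other genes fell between arrays. Their mean was then -0.04 (-0.09 at 12 h), and nearly all of the size belongs to Egr1. A high untreated level is argued against by the mean against 0 at 24 h, -0.325, and by the untreated mean of -0.41. The cameraPR adjusted p of 4.91e-21 compares the list with other genes on values against 0 and does not measure the spread between arrays. A dye bias stays open: the turned list mean lay below 0 in 8 of 8 arrays, which was written beforehand as evidence against it but also follows from such a bias if the turning is wrong, and within each dye the difference from the untreated arrays was -0.331 in Cy5 and 0.144 in Cy3 (mean -0.094, exact permutation p = 0.640 turned, 0.213 not turned and 0.413 by size alone). No biological explanation was tested; ERK targets as a list were called higher at 2 h (adjusted p = 0.0234), when Egr1 fell.

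The 35 splits of the 7 arrays of each comparison show whether chance could give the counts. The real split is included here and in the counts of splits below. At 1 h 36 probes compare with 16 in the highest other split, and 1 split, the real one, reached that count. The same held at 2 h (101, highest other 2), 4 h (39, highest other 1) and 5 days (390, highest other 170). This argues against chance there but does not exclude it. The top rank among 35 splits is the most this test can give. Every time was tried, without correction for their number, and the test was chosen after the result was seen. At the remaining times the splits do not argue against chance. At 12 h 6 splits reached the real 3 (highest other 17), and at 24 h 9 reached 5 (highest other 46). At 3 days 19 reached 132 (highest other 3238), and at 7 days 4 reached 196 (highest other 437). The split with 3238 calls set both Cy3 arrays of 3 days with the untreated Cy5 array, so it parts each group by dye in opposite directions, and the split of all Cy5 from all Cy3 arrays gave 1808. This points to a structure of the arrays; with a dye effect for each group the real count at 3 days was 444 and at 7 days 484. In 100 splits of all arrays or of the times compared, 1 each, the real one, reached the counts of probes. These were 962 at any time (highest other 6) and 105 between early and middle times (highest other 0). They were 603 between middle and late times (highest other 164) and 1167 between early and late times (highest other 180). This argues against chance for these counts. The real split alone also reached the 52 list calls, but another split gave 48. Nearly as many lists were thus called at the preset correlation without the real groups, so chance is not excluded for the list calls.

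Single arrays stood apart from the other 3 of their group in 11 of 183 groups checked, and chance marks about 1 in 20 groups. The number of values was 18951 on 12h replicate 2, against 19388 to 19464 on the others. On 7d replicate 2 it was 18331, against 18668 to 18725. Cfap206 lay at 1.798 on 2h replicate 3, against -0.359 to -0.008. Adamts1 lay at -0.926 on 2h replicate 2, against -1.868 to -1.738. Eno1b lay at 0.7 on 4h replicate 4, against 0.998 to 1.044. 4921536K21Rik lay at 5.082 on 7d replicate 4, against 1.252 to 1.796. Vim lay at -1.314 on 5d replicate 4, against -1.167 to -1.137. Saa3 lay at 2.965 on 5d replicate 3, against 1.673 to 1.881. Eng lay at 1.886 on 5d replicate 1, against 1.487 to 1.538. The mean of the G2/M list was 0.319 on 2h replicate 1, against 0.238 to 0.251, and 0.03 on 5d replicate 3, against -0.363 to -0.329.

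Values differed between parts of the course, by a test of the difference itself. The arrays differ in time under tetracycline, and the labels name no untreated culture of the same time, so the cause of these differences was not tested. The numbers of probes were 105 between early and middle, 603 between middle and late and 1167 between early and late times. From early to middle times Col1a2 differed by 1.22, Sparc by 1.15, Adamts1 by 1.14, Atoh8 by 1.10, Ier3 by -1.43, Psat1 by -1.24, Gsto1 by -1.06 and Hspa5 by -1.04. From middle to late times Lox differed by 1.91, Postn by 1.89, Ccdc80 by 1.82, Dcn by 1.77, Abhd12 by -2.09, Sema4a by -1.77, Ccna2 by -1.77 and S100a4 by -1.64. From early to late times Adamts1 differed by 2.75, Lox by 2.64, Dcn by 2.49, Postn by 1.94, Psat1 by -2.37, Tm4sf1 by -2.14, Hmgcs1 by -1.98 and Ctsl by -1.93.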

How the results depend on the processing

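The dye effect for each group, array weights, rows as deposited, ceiling values kept, arrays not turned and the tests without 5 and 7 day arrays were chosen only after the result was seen. Signal over background is not given by the files, so weak features could not be set apart, and with 4 arrays a time the counts depend on the settings below; unless stated, the cause was not tested. Among 153 results for named genes, robust eBayes left 151 on their side of the threshold, ceiling values kept 149, a dye effect for each group 144 and no dye term 134, with signs unchanged under these 4. Calls were lost for 76 with values not centred, 44 with quantile normalization, 18 with array weights, 18 with the replicate block and 276 of 969 values with single arrays left out, again with no sign turned. They were lost for 119 of 119 with only the arrays of the 2 groups compared, 63 of 150 with rows as deposited (5 more turned sign) and 14 of 119 against 0 (3 more turned sign).

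Counts of probes moved as follows. A dye effect for each group gave 96 for 1 h, 240 for 2 h, 89 for 4 h, 33 for 12 h, 20 for 24 h, 444 for 3 days, 622 for 5 days, 484 for 7 days, 1664 for any time, 203 for early to middle, 1014 for middle to late and 27 for the untreated arrays. Testing against 0 gave 162 for 1 h, 519 for 2 h, 203 for 4 h, 53 for 12 h, 56 for 24 h, 1165 for 3 days, 1074 for 5 days, 1157 for 7 days and 1471 for any time. Array weights gave 963 for 1 h, 1518 for 2 h, 691 for 4 h, 707 for 12 h, 716 for 24 h, 686 for 5 days, 303 for 7 days, 1987 for any time, 555 for early to middle and 1043 for the untreated arrays. Averaged dye pairs, with fewer replicates, gave 72 for 1 h, 238 for 2 h, 77 for 4 h, 19 for 12 h, 28 for 24 h, 642 for 3 days, 814 for 5 days, 619 for 7 days, 173 for early to middle, 943 for middle to late and 59 for the untreated arrays. Both untreated pairs held the same merged Cy5 array, so they were not independent. Their spread is understated, and the counts that use the untreated arrays are not a fair comparison. A minimum of 1 value gave 61 for 1 h, 67 for 4 h, 29 for 12 h, 39 for 24 h, 206 for 3 days and 47 for the untreated arrays. No dye term gave 8 for 24 h, probes measured on all arrays gave 10 for 24 h, and leaving out the 5 and 7 day arrays gave 389 for any time. With only the arrays of the 2 groups compared, which leaves few degrees of freedom, limma called 0 at all 8 times, with 1115 at 1 h, 1634 at 2 h, 1010 at 4 h, 807 at 12 h, 850 at 24 h, 649 at 3 days, 1324 at 5 days and 942 at 7 days at an unadjusted p under 0.05. Chance alone gives a share of 0.05 of the probes tested, and the counts at 12 h, 24 h and 3 days lie below it. The estimated correlation gave 23 list calls instead of 52.

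Replicate numbers did not pair arrays across groups beyond their dye. Of 32 arrays, 15 fitted best with their own number, but a number also fixes the dye. The median correlation of deviations from the group means was 0.03 for the same number. It was 0.024 for another number of the same dye and -0.029 for the other dye. With the replicate block in place of the dye term there were 25 for 4 h and 4 for the untreated arrays.

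Scaling changed the balance of directions. Values not centred gave 14 for 1 h (2 higher, 12 lower), 14 for 2 h (7 higher, 7 lower), 4 for 4 h (1 higher, 3 lower), 1 for 12 h (0 higher, 1 lower), 1 for 24 h (0 higher, 1 lower), 21 for 3 days (14 higher, 7 lower), 120 for 5 days, 30 for 7 days (12 higher, 18 lower), 457 for any time, 48 for early to middle (18 higher, 30 lower), 293 for middle to late, 687 for early to late and 6 for the untreated arrays. Quantile normalization gave 182 for 1 h, 332 for 2 h (215 higher, 117 lower), 199 for 4 h, 40 for 12 h, 15 for 24 h (12 higher, 3 lower), 4 for 3 days (3 higher, 1 lower), 68 for 7 days (25 higher, 43 lower), 353 for early to middle, 374 for middle to late (167 higher, 207 lower) and 80 for the untreated arrays (56 higher, 24 lower), and at 5 days 88 higher and 182 lower. The main splits were 10 higher and 26 lower for 1 h, 77 higher and 24 lower for 2 h, 27 higher and 12 lower for 4 h, 1 higher and 2 lower for 12 h, 3 higher and 2 lower for 24 h, 68 higher and 64 lower for 3 days, 220 higher and 170 lower for 5 days, 108 higher and 88 lower for 7 days, 28 higher and 77 lower for early to middle, 343 higher and 260 lower for middle to late and 2 higher and 12 lower for the untreated arrays.

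With single arrays, or a replicate of every group, left out, counts ran from 19 to 386 for 1 h, 44 to 424 for 2 h, 10 to 312 for 4 h, 2 to 330 for 12 h, 4 to 274 for 24 h, 22 to 805 for 3 days, 204 to 864 for 5 days, 70 to 698 for 7 days, 528 to 640 for any time, 39 to 51 for early to middle, 379 to 396 for middle to late, 765 to 920 for early to late and 1 to 3 for the untreated arrays. Leaving out untreated replicate 1 leaves untreated arrays of a single dye.

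Rows as deposited gave 19 for 1 h, 39 for 2 h, 7 for 4 h, 10 for 24 h, 87 for 5 days, 56 for early to middle, 274 for middle to late, 760 for early to late and 31 for the list tests, and turned the sign of Pomgnt1 at 5 days (0.17), S100a6 at 5 days (0.32), Ncbp1 at 7 days (0.37), Vim at 5 days (0.16) and Calr at 5 days (-0.19). Against 0, Zkscan1 turned at 1 h (-0.20), 2 h (-0.17) and 4 h (-0.18).

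Arrays not turned changed the most signs, because the Cy3 arrays then count with the opposite sign. Counts were 178 for 1 h, 152 for 2 h, 172 for 4 h, 312 for 12 h, 200 for 24 h, 2689 for 3 days, 885 for 7 days, 0 for early to middle, 37 for middle to late, 617 for the untreated arrays and 0 for the list tests. For the counts of 0, 375 probes from early to middle times and 8 list tests had an unadjusted p under 0.05 (limma and cameraPR). Both lie below the share of 0.05 of the tests that chance alone gives. Of the 153 results for named genes, 39 kept their sign but not their call and 114 turned. At 1 h the values were -1.46 for H1f10, -0.48 for Epb41l3, -0.95 for Max, -0.22 for Gapdh, -0.38 for Mid1, 0.43 for Adamts1, 0.24 for Dcn, 0.31 for Postn, 0.25 for Lox, 0.83 for Naprt and 0.060 for Col1a1. At 2 h the values were -1.68 for Son, -1.23 for Cfap206, -0.45 for Snrnp70, -0.25 for Gapdh, -0.55 for Mt1, 0.54 for Egr1, 0.58 for Postn, 0.84 for Adamts1, 0.42 for Col3a1, 0.39 for Lox, -0.34 for Actb, -0.44 for Pfn1, -0.069 for Hsp90aa1, -0.21 for Sdhd and -0.34 for Actc1. At 4 h the values were -2.13 for Xbp1, -0.13 for Tm4sf1, -0.31 for Gapdh, -0.55 for Matr3, -0.25 for Eno1b, 0.88 for Egr1, 0.44 for Glmp, 0.49 for Adamts1, 0.70 for Postn, 0.084 for Cpz and 0.62 for Naprt. At 12 h the values were 1.10 for Egr1 and 0.23 for Postn. At 24 h the values were -0.44 for Mid1, 0.60 for Egr1 and 0.38 for Postn. At 3 days the values were -2.89 for Cfap206, -1.55 for Wdr60, -1.72 for H1f10, -0.71 for Mib1, -1.61 for Nup214, 0.58 for Wdr36, 0.56 for Neu1, 0.27 for Aamp, 0.47 for Fabp5, 0.79 for Dnajc3, 0.85 for Egr1 and -0.44 for Perp. At 5 days the values were -1.32 for Xbp1, -0.58 for Egfr, -1.13 for Rgs19, -1.65 for Man1b1, -0.25 for Klhdc7a, -1.65 for Them7, 0.72 for Pomgnt1, 0.28 for Pdcd1, 0.62 for Psat1, 0.033 for S100a6, -0.034 for Mmp2, 0.15 for Vim, 0.48 for Npm1, 0.13 for Rpl13a, 0.52 for Rpl14, 0.59 for Rpl4, 0.41 for Rps20, -0.18 for Calr, 0.065 for Hspe1, 0.47 for Hspd1, -0.55 for H2-K1, -0.38 for Saa3, 0.44 for Uqcrh, 0.18 for Cdh5 and 0.35 for Ppia. At 7 days the values were -1.35 for Txnrd2, -3.40 for 4921536K21Rik, -0.43 for Rtf1, -1.79 for Xbp1, -1.85 for Acbd3, 0.98 for Ncbp1, 0.26 for Gprc5c, 1.20 for Psat1, -0.091 for Btg2, -0.40 for Rrm2, 0.27 for Mcm5, 0.46 for Mmp9 and 0.23 for Scd1. From early to middle times the values were -0.15 for Col1a2, -0.16 for Sparc, -0.073 for Adamts1, -0.11 for Atoh8 and 0.22 for Gsto1. From middle to late times the values were -0.10 for Lox, -0.047 for Postn, -0.091 for Ccdc80, -0.093 for Dcn and 0.95 for Abhd12. From early to late times the values were -0.039 for Adamts1, -0.064 for Lox, -0.27 for Postn and 0.30 for Psat1. In the untreated arrays the values were 0.82 for Htra1, 0.090 for Tapt1, 0.81 for Max, 1.95 for Kcnu1, 0.42 for Itsn1, 1.68 for Son, 0.84 for Cfap206 and 1.24 for Xbp1.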

Other observations

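No further test was chosen for this part after a result was seen. Of the 28 lists, 17 were called at 1 time or more and 11 at no time by cameraPR. Markers of other cell types were among the latter: epithelial markers had a smallest adjusted p of 0.298 (13 genes, median -0.22 at 1 h), endothelial and muscle markers 0.298 (14 genes, median 0.05 at 2 h), immune and blood cell markers 0.642 (8 genes, median 0.04 at 12 h) and liver and nerve markers 0.327 (10 genes, median -0.10 at 2 h). Single members did pass, such as the muscle actin Actc1, which rose by 1.13 at 2 h (SE 0.25, adjusted p = 0.0245).

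Lists of growth arrest and cell death genes were not called either, while the G1/S, G2/M and ERK target lists were called at some times. CDK inhibitors and p53 targets had a smallest adjusted p of 0.685 (16 genes, median -0.04 at 12 h), quiescence and FOXO targets 0.133 (17 genes, median 0.21 at 7 days) and BCL2 family and caspase genes 0.504 (18 genes, median 0.18 at 2 h). Matrix proteases and their inhibitors, which hold Adamts1, Mmp2 and Mmp9, had 0.149 (15 genes, median 0.18 at 5 days). Interferon response genes had 0.211 (19 genes, median -0.09 at 24 h), chemokines and NF-kB targets 0.145 (10 genes, median 0.12 at 5 days), and TGF-beta and BMP targets 0.395 (14 genes, median -0.14 at 7 days).

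In the untreated arrays Kcnu1 averaged -2.03 against 0, Tapt1 -1.97, Cfap206 -1.60, Max and Itsn1 -1.42 each, Htra1 -0.90 and Calml3 0.58.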
